A study of Homo sapiens with 12 samples.

How the data were processed

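RNA of BE2C cells was measured by polyadenylated RNA sequencing in 12 libraries, 3 for each combination of genotype (wildtype, LIN28B knockout) and fraction (input, polysome), as given per the labels. Per the submitters' processing notes the authors used kallisto 0.44.0 and DESeq2 1.24.0 with the hg38 build. The annotation, the filters, the step from transcripts to genes and the strand of the libraries are not given in the sources used here. Genes that overlap another gene on either strand are therefore uncertain, LIN28B and MYCN among them, each of which has an antisense gene. RN7SL1 and RN7SL2 are near-identical, and 106 genes had values identical to those of another gene.

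The signal values deposited by the authors are estimated counts per gene divided by the authors' normalisation factors, which are not given. They have decimals, and only 8.3 to 70.1% of low values per library lay within 0.1 of a whole multiple of one step, so whole reads were not recovered and sequencing depth is unknown. In the deposited comparison the authors give a log2 fold change with its standard error from their model, which by its values is the interaction of genotype and fraction, wildtype relative to knockout. The score deposited by the authors is the test statistic of that model and was not used. The p-value columns deposited by the authors hold raw and adjusted p-values of that model, with 1405 of 15505 genes lacking the adjusted one. The deposited mean signal equals the mean of the 12 libraries.

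Each column was assigned to a library by its name and 0 columns were left over. Of 29207 genes, 16367 with a normalised count of at least 10 in at least 3 libraries were tested. Values were taken as log2 of the normalised count plus 1, which understates fold changes of weakly measured genes. limma 3.58.1 in R 4.3.3 fitted 4 group means to all 12 libraries (lmFit, eBayes with a trend in the variance, 8 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over genes within each comparison, with a threshold of 0.05. The comparisons were knockout against wildtype in input and in polysome, the interaction of genotype and fraction (polysome association), and polysome against input within each genotype. The design, the filter, the threshold, the alternatives and the gene lists were fixed before the data were examined.

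The text names, for input, polysome and polysome association, the 6 genes that rose and the 6 that fell with the largest log2 fold change. They had to pass the threshold, have a mean of at least 100 in a compared group, show no overlap between the compared libraries and carry a symbol that is not a clone or accession name. For polysome against input in wildtype 5 and 5 were named by the same rule. For polysome association, overlap was judged on the log2 polysome to input ratios of same-numbered libraries. LIN28B and MYCN were named in every comparison, and examples from lists come from the 4 members of smallest p unless stated.

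Of 33 fixed gene lists with 1064 symbols, 997 symbols were found and 67 were not. Lists with at least 5 tested members were tested with limma camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison by the Benjamini-Hochberg method. The lists of epithelial markers (4 tested members) and of blood cell markers (3) were too small to test. Alternatives were camera with the correlation estimated from the data and fry, a rotation test of whether the members of a list differ from no change, where camera compares them with the other genes. Coordinates, gene types, transcript GC content and lengths came from GENCODE release 29 on GRCh38, with 27794 genes matched.

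Alternatives set beforehand were pseudocounts of 0.5 and 5, no filter, a filter on a mean of at least 100, upper quartile scaling, quantile normalization, median ratio scaling within each fraction, only the 6 libraries compared, the replicate number as a block, robust variance and leaving out each library in turn. Correction of each library for GC content and transcript length by splines with 4 degrees of freedom, on 16052 genes, was added after the results were seen. Coding length was not part of that correction. The fit was tested on simulated data with 50 changed genes per fold. At 1.5-fold 86% were recovered in input, 90% in polysome, 74% in polysome association, 88% in the wildtype and 80% in the knockout fraction comparison. At 2-fold 96% were recovered in polysome association and 100% elsewhere. False calls were 15 of 208, 9 of 204, 10 of 195, 18 of 212 and 10 of 200. The 1 shifted list and 0 others of 21 simulated lists were called. Changed genes were drawn from genes with a mean count of at least 50, and every gene had the same dispersion. Only a small share of the genes was changed. The simulation therefore covers neither weakly measured genes nor comparisons in which most genes change. Simulated genes also varied independently of each other, so the simulation does not cover lists of correlated genes. In the real lists the estimated correlation reached 0.702 for cytosolic ribosomal proteins and 0.766 for mitochondrial DNA genes. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and figures with matplotlib 3.10.9.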

Results

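BE2C is a human neuroblastoma cell line with many copies of the oncogene MYCN. Polyadenylated RNA was sequenced from BE2C cells with intact LIN28B and from cells in which LIN28B was knocked out. LIN28B is an RNA-binding protein that blocks the maturation of let-7 microRNAs and also binds mRNAs. From each genotype the labels name 3 libraries of input RNA (unfractionated) and 3 of polysome RNA, the RNA recovered with several ribosomes attached, which gives 12 libraries in 4 groups. The question set by the labels is how loss of LIN28B changes the RNAs carried by polysomes. Nothing in the sources says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The deposited normalised counts summed to between 11678452 and 11899959 in the libraries labelled wildtype input, 11743967 and 12033596 in knockout input, 11449222 and 11825699 in wildtype polysome and 13908625 and 14191796 in knockout polysome. The number of sequenced reads behind them is unknown.

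The RNA of LIN28B itself was lower in knockout input and not in knockout polysome. LIN28B (chromosome 6, 104936616 to 105083332, GRCh38) stood at 7065, 7361 and 7403 normalised counts in wildtype input and at 4061, 4107 and 4190 in knockout input. It stood at 6617, 4405 and 4674 in the libraries labelled wildtype polysome and at 5541, 5661 and 6136 in those labelled knockout polysome. In input the knockout was 1.77-fold lower (log2 fold change -0.82, SE 0.11, adjusted p = 1.26e-04 with limma and Benjamini-Hochberg adjustment). In polysome the log2 fold change was 0.17 with an SE of 0.11 (adjusted p = 0.19 with limma and Benjamini-Hochberg adjustment). Without wildtype polysome library 1 this value was 0.35 and passed, and with correction for GC content and length it was 0.43 and passed (adjusted p = 0.00286, limma). Quantile normalization turned it to -0.21, which did not pass. Upper quartile scaling gave -0.03, as it moved the median over all genes by -0.19. The labels do not give the edited site, and RNA with a small edit is still counted, so the level is only a partial check. Because the polysome values go against the genotype labels, polysome groups are named below as the libraries labelled so, and each direction drawn from them rests on those labels. MYCN (chromosome 2, 15940564 to 15947007) was at 33890 ± 409 in wildtype input and 35030 ± 1170 in knockout input (SD, n = 3).

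**Figure D1:**
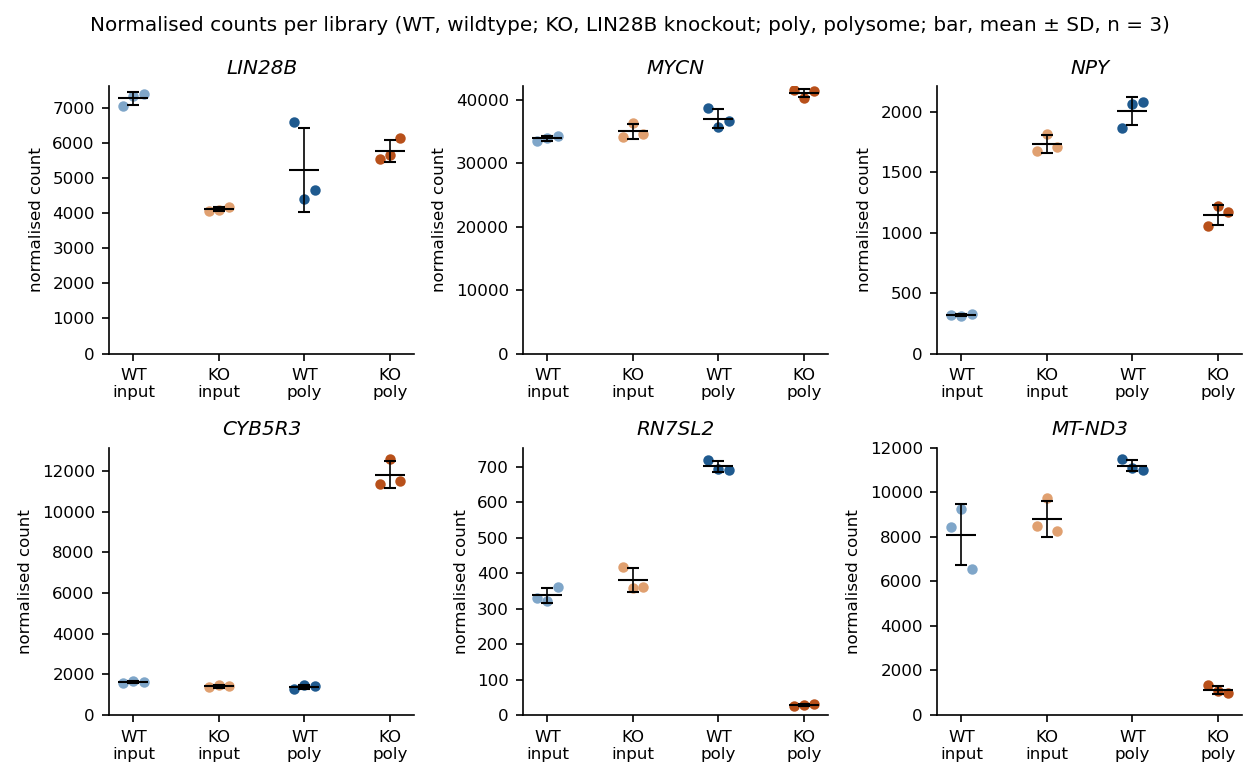
Normalised counts of 6 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars). LIN28B fell from 7277 to 4119 between the input groups but not between the polysome groups, CYB5R3 stood out in the libraries labelled knockout polysome at 11810, and NPY was low in wildtype input alone at 319.2.

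In input RNA, where the comparison asks what LIN28B loss changes in the whole RNA pool, the largest falls were those of KIRREL1, LCP1 and CRB2 and the largest rises those of MAGEA12, RNF152 and GDNF. KIRREL1, an adhesion molecule of the cell junction (chromosome 1, 157993273 to 158100262), fell 23.6-fold, from 226 ± 39.5 to 8.61 ± 1.76 normalised counts (SD, n = 3). LCP1, an actin-bundling protein, fell 16.2-fold, CRB2, a polarity protein, 8.91-fold, and the basement membrane collagens COL4A2 and COL4A1 fell 7.90-fold each. C20orf204 fell 5.59-fold. NPY, the neuropeptide Y gene (chromosome 7, 24284163 to 24291865), rose 5.41-fold, from 319 ± 7.43 to 1733 ± 76.7 normalised counts (SD, n = 3). MAGEA12, a cancer-testis antigen, rose 8.53-fold, RNF152 6.49-fold, GDNF, the growth factor that signals through RET, 5.54-fold, CA12, a carbonic anhydrase, 4.87-fold, and the immunoglobulin heavy-chain gene IGHM 4.82-fold. The largest adjusted p among these 12 genes was that of COL4A1, 4.84e-04 (limma, Benjamini-Hochberg adjustment). Lack of overlap between the 3 knockout and the 3 wildtype values was a condition for naming them. Most of them stood near knockout input in the libraries labelled wildtype polysome too, with means of 6.39 for KIRREL1, 11.3 for LCP1, 22.7 for CRB2 and 2005 for NPY. MAGEA12, at 38.4 there, stayed nearer to wildtype input (14.4) than to knockout input (129). An effect of LIN28B loss on most of these genes can therefore not be told apart from a state of the wildtype input libraries. MYCN did not pass (log2 fold change 0.05, adjusted p = 0.519 with limma and Benjamini-Hochberg adjustment).

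Among 16367 tested genes, 1663 rose and 1083 fell in knockout input (limma, Benjamini-Hochberg adjusted p below 0.05). With upper quartile scaling 1183 rose and 1508 fell, against a median shift of -0.05 over all genes. Without wildtype input library 1, or without knockout input library 2, the total dropped to 1609 or 1608.

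In knockout input 24 of 31 proteasome genes rose and 0 fell, led by PSMD1 (1.42-fold), PSMD13 (1.35-fold) and PSMD11 (1.65-fold), and 28 rose and 0 fell when adjusted over the list alone. Among 29 S phase genes 18 rose, 0 fell and 11 did not pass, with FEN1 at 1.49-fold, RRM1 at 1.35-fold, MCM6 at 1.31-fold and PCNA at 1.39-fold (23 rose and 0 fell adjusted over the list alone). Among 33 mitotic genes 19 rose and 1 fell, with CCNB1 at 1.37-fold and BIRC5 at 1.36-fold (25 and 2 adjusted over the list alone). Among 36 MYC target genes 19 rose and 1 fell, with NME1 at 1.45-fold and CDK4 at 1.30-fold (23 and 1 adjusted over the list alone). Among stress genes, 13 of 32 genes of ATF4 and the unfolded protein response rose and 0 fell (17 and 1 adjusted over the list alone), with CHAC1 at 2.25-fold and DDIT4 at 1.73-fold. Of 17 immediate early and heat shock genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), with EGR1 at 2.21-fold and HSP90AA1 at 1.58-fold. Of 33 extracellular matrix and adhesion genes 12 fell and 3 rose (15 and 4 adjusted over the list alone), with LAMC1, a laminin, 1.53-fold lower and COL6A1 1.63-fold lower. The limma camera test passed for these 7 lists at its preset correlation, with Benjamini-Hochberg adjusted p from 4.53e-15 for the proteasome to 3.48e-04 for extracellular matrix. The adjusted p with an estimated correlation was 0.21 for the proteasome, mitotic, stress-response, immediate early and extracellular matrix lists and 0.24 for the S phase and MYC target lists.

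More rises than falls passed in 8 further lists. Of 78 mitochondrial ribosomal protein genes 26 rose and 0 fell (39 and 0 adjusted over the list alone), with MRPS11 1.51-fold higher, and of 76 nuclear-encoded respiratory subunits 15 and 0 (20 and 0 adjusted over the list alone). Of 50 ribosome biogenesis genes 15 rose and 0 fell (20 and 1 adjusted over the list alone), with LTV1 1.45-fold higher, and of 29 translation initiation factors 14 and 0 (17 and 0 adjusted over the list alone), with EIF4E 1.39-fold higher. Of 36 spliceosome genes 15 rose and 1 fell (22 and 1 adjusted over the list alone), and of 22 glycolysis genes 10 and 1 (12 and 1 adjusted over the list alone). Of 19 aminoacyl-tRNA synthetases 6 rose and 0 fell (6 and 0 adjusted over the list alone) and of 36 genes of ER translocation and secretion 9 and 3 (13 and 4 adjusted over the list alone). Falls were counted for 8 of 27 lysosome genes, with LIPA 1.42-fold lower, 5 of 21 snoRNA host RNAs, with GAS5 1.21-fold lower, and 2 of 15 nuclear-retained RNAs, with NORAD, which is known to act mainly in the cytoplasm, at a log2 fold change of -0.31 and MALAT1 1.49-fold lower (8, 5 and 2 adjusted over the list alone), and no member of these 3 lists rose. The values of MALAT1 overlapped between the genotypes, and its call ended with robust variance (adjusted p = 0.0591) and without each of 4 single input libraries (adjusted p from 0.0544 to 0.11, limma). These 11 lists passed by limma camera with Benjamini-Hochberg adjusted p from 4.73e-10 for mitochondrial ribosomal proteins to 0.0361 for snoRNA hosts. With an estimated correlation the adjusted p was 0.24 for mitochondrial ribosomal proteins, initiation factors, glycolysis and synthetases, 0.36 for respiratory subunits, 0.21 for nuclear-retained RNAs and 0.31 for the other 5. The calls of the synthetase and the ER lists ended under upper quartile scaling, quantile normalization and a mean count of at least 100 (limma camera adjusted p from 0.0939 to 0.297), and that of the ER list also without knockout input library 2 (adjusted p = 0.0579) and with correction for GC content and length (adjusted p = 0.053, with the median at 0.12 after and 0.09 before it). The call of nuclear-retained RNAs ended with that correction (adjusted p = 0.169, with the median at -0.17 after and -0.19 before it) and without wildtype input library 1 (adjusted p = 0.052), and that of snoRNA hosts without input library 3 of either genotype (adjusted p = 0.0749 and 0.0944), all by limma camera.

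In total 19 of 31 lists passed in input at the preset correlation, and 0 did with an estimated one (lowest adjusted p = 0.21 by limma camera). The list of mitochondrial DNA genes, translated inside mitochondria, had 6 members that fell and 7 that did not pass, with MT-CYB 1.35-fold lower (8 fell and 0 rose adjusted over the list alone; adjusted p = 1.79e-05 by limma camera with Benjamini-Hochberg adjustment, and adjusted p = 0.31 with an estimated correlation), and its median of -0.22 moved to 0.00 under quantile normalization. The 78 cytosolic ribosomal protein genes did not pass as a list (adjusted p = 0.153, limma camera), with 4 members that rose and 1 that fell. The LIN28 and let-7 axis did not pass either (adjusted p = 0.59, limma camera): 6 of its 35 members rose and 6 fell, with IGDCC3 2.92-fold lower and AURKB 1.35-fold higher.

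In the polysome comparison the libraries labelled knockout polysome differed from those labelled wildtype polysome in most tested genes. CYB5R3, a cytochrome b5 reductase (chromosome 22, 42617840 to 42649568), stood at 11810 ± 673 against 1386 ± 86.2 normalised counts (SD, n = 3), 8.52-fold higher. IL10RB, a cytokine receptor chain, was 10.5-fold higher, the noncoding RNA H19 10.03-fold, PRR36 8.69-fold and CAPN6 7.75-fold. The splicing factor SF3A2 stood at 6816 ± 755 against 848 ± 37.1 (SD, n = 3). In the other direction RN7SL2, an RNA component of the signal recognition particle that is not translated (chromosome 14, 49862550 to 49862849), stood at 28.0 ± 2.86 against 701 ± 15.3, 24.3-fold lower. RN7SL1, a near-identical copy that shares reads with it, was 13.4-fold lower, ANKRD10-IT1 10.6-fold, MT-ND3, a mitochondrial DNA gene, 9.99-fold, ZNF471 8.39-fold and TCTE3 8.07-fold. These 12 genes had adjusted p of at most 5.44e-08 (limma, Benjamini-Hochberg adjustment). Sequencing was of polyadenylated RNA, and how evenly the libraries captured RN7SL1, RN7SL2 or the histone RNAs described below was not measured. MYCN was 1.11-fold higher (adjusted p = 8.63e-03, limma with Benjamini-Hochberg adjustment), a direction that turned under upper quartile scaling, which moved the median of all genes by -0.19, and under correction for GC content and length (-0.14, adjusted p = 0.0275, limma), and a call that ended under quantile normalization (adjusted p = 0.194, limma).

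Of 16367 genes, 5213 rose and 4713 fell in the libraries labelled knockout polysome (limma, Benjamini-Hochberg adjusted p below 0.05). Upper quartile scaling shifted the median over all genes by -0.19 and gave 3875 that rose and 6195 that fell. After correction for GC content and length, on 16052 genes, 5036 rose and 3616 fell. By that fit 7021 of the 9926 genes called in polysome stayed called, against 9766 on the same genes uncorrected. Across 9876 genes the change rose with transcript GC content (Spearman rho 0.43) and with coding length (Spearman rho 0.41), where genes are not independent replicates.

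Of 19 aminoacyl-tRNA synthetases, the enzymes that load tRNAs, 15 rose and 1 fell in the libraries labelled knockout polysome (15 and 1 adjusted over the list alone), with IARS 2.86-fold, AARS 3.17-fold and VARS 3.04-fold higher. Of 22 glycolysis genes 15 rose and 0 fell (15 and 0 adjusted over the list alone), with PKM 3.18-fold and HK1 3.05-fold higher. Of 76 nuclear-encoded respiratory subunits 57 fell and 12 rose (57 and 12 adjusted over the list alone), with NDUFA5 3.78-fold and COX7A2 3.21-fold lower and ATP5F1B 1.93-fold higher. Of 78 cytosolic ribosomal protein genes 58 fell and 9 rose (58 and 9 adjusted over the list alone), with RPS29 3.86-fold and RPS21 3.06-fold lower and RPS13 3.41-fold higher. Of 21 snoRNA host RNAs 18 fell and 0 rose (18 and 0 adjusted over the list alone), with SNHG3 7.15-fold and SNHG4 4.87-fold lower. Of nuclear-retained RNAs, 12 of 15 fell and 2 rose (12 and 2 adjusted over the list alone), with MIR17HG 7.26-fold and NEAT1 3.38-fold lower. MALAT1, not among the 4 members of smallest p, was higher by a log2 of 1.04. At the preset correlation the limma camera test gave Benjamini-Hochberg adjusted p of 1.25e-06 for the synthetases, 4.92e-06 for glycolysis, 2.71e-10 for respiratory subunits, 3.11e-10 for ribosomal proteins, 5.43e-10 for snoRNA hosts and 7.68e-05 for nuclear-retained RNAs. With an estimated correlation the synthetases, snoRNA hosts and nuclear-retained RNAs had adjusted p = 0.031 each, and adjusted p was 0.24 for glycolysis, 0.47 for respiratory subunits and 0.56 for ribosomal proteins. Correction for GC content and length ended the call of the ribosomal proteins (median -0.005, adjusted p = 0.513 by limma camera).

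Of 17 immediate early and heat shock genes 16 rose and 0 fell (16 and 0 adjusted over the list alone), with EGR1 4.31-fold and HSPA1A 2.33-fold higher. Of 33 extracellular matrix and adhesion genes 19 rose and 1 fell (19 and 1 adjusted over the list alone), with CDH11 3.14-fold higher. Of 29 S phase genes 22 rose and 4 fell (23 and 4 adjusted over the list alone), with RRM1 2.57-fold higher, and of 33 mitotic genes 19 and 6 (19 and 8 adjusted over the list alone). Of 36 MYC targets 21 rose and 5 fell (21 and 6 adjusted over the list alone), with CAD 2.62-fold higher and HSPE1 3.61-fold lower, and of 32 genes of ATF4 and the unfolded protein response 18 and 6 (18 and 6 adjusted over the list alone). Of 50 ribosome biogenesis genes 29 rose and 10 fell (29 and 10 adjusted over the list alone), with UTP20 3.85-fold higher. Of 29 initiation factors 19 rose and 8 fell (19 and 8 adjusted over the list alone), with EIF4G1 2.54-fold higher and DENR 2.31-fold lower. Of 78 mitochondrial ribosomal protein genes 41 fell and 13 rose (43 and 13 adjusted over the list alone), with MRPL32 3.74-fold lower and MRPL10 3.49-fold higher. Of 15 replication-dependent histone genes 7 fell and 0 rose (6 and 0 adjusted over the list alone), with HIST1H2BH 3.37-fold lower. These 10 lists passed by limma camera at the preset correlation, with Benjamini-Hochberg adjusted p from 9.55e-05 for immediate early genes to 0.0259 for mitotic genes. With an estimated correlation the adjusted p was 0.31 for immediate early genes, 0.24 for extracellular matrix and histones, 0.47 for the ATF4 list, 0.56 for S phase and initiation factors, 0.67 for ribosome biogenesis and 0.61 for mitotic genes, MYC targets and mitochondrial ribosomal proteins. Quantile normalization turned the medians of the ATF4 and mitotic lists to -0.04 and -0.07 and ended the calls of MYC targets (adjusted p = 0.843), ribosome biogenesis (adjusted p = 0.804), initiation factors (adjusted p = 0.785), histones (adjusted p = 0.339), extracellular matrix (adjusted p = 0.073) and S phase genes (adjusted p = 0.0525), by limma camera. Correction for GC content and length turned that of mitochondrial ribosomal proteins to 0.09 and ended the calls of extracellular matrix (median 0.53 before and 0.16 after, adjusted p = 0.35) and histones (median -0.89 before and -0.28 after, adjusted p = 0.179, limma camera). With a mean count of at least 100 the calls of the ATF4, mitotic, MYC target, extracellular matrix, ribosome biogenesis and initiation factor lists ended (limma camera adjusted p from 0.125 to 0.265), and upper quartile scaling ended those of the ATF4 and mitotic lists (adjusted p = 0.113 each) and of ribosome biogenesis (adjusted p = 0.069). Without wildtype polysome library 2 the call of the mitotic list ended (adjusted p = 0.053, limma camera).

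In total 16 of 31 lists passed in polysome at the preset correlation and 3 with an estimated one. Fibroblast and stromal markers, of which 6 of 10 rose and 1 fell (6 and 1 adjusted over the list alone) with a median of 0.58 beside the 0.53 of the matrix list (COL1A1, COL1A2 and COL3A1 stand on both lists), did not pass as a list (adjusted p = 0.206, limma camera). Neither did Schwann and glial markers, with 1 of 5 that rose and 2 that fell (adjusted p = 0.23, limma camera).

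The change in polysome association was taken as the polysome to input ratio in the knockout relative to that in the wildtype, each polysome group as labelled. Its largest rises belonged to genes that were high in wildtype input and low in the other 3 groups. KIRREL1 rose 58.0-fold in this ratio (log2 5.86, SE 0.49), with 226 ± 39.5 normalised counts in wildtype input, 6.39 ± 3.80 labelled wildtype polysome, 8.61 ± 1.76 in knockout input and 15.8 ± 2.64 labelled knockout polysome (SD, n = 3). LCP1 rose 31.1-fold, CRB2 13.9-fold, COL4A2 12.3-fold and COL4A1 10.7-fold. TMEM8B, by contrast, rose 11.3-fold mainly through a mean of 950 counts in the libraries labelled knockout polysome, against 138 in those labelled wildtype polysome. Its lower mean in knockout input (133) than in wildtype input (215) added to the ratio. The largest falls were those of RN7SL2 (27.2-fold), RNF152 (23.7-fold), RN7SL1 (19.2-fold), MT-ND3 (10.97-fold), NPY (9.46-fold) and ANKRD10-IT1 (9.01-fold). Adjusted p was at most 4.12e-04 for these 12 genes (limma, Benjamini-Hochberg adjustment). LIN28B rose 1.98-fold (adjusted p = 6.21e-05) and MYCN had a log2 value of 0.10 (adjusted p = 0.197), both by limma with Benjamini-Hochberg adjustment. MYCN turned to -0.23 and passed with correction for GC content and length (adjusted p = 0.0182, limma), and turned to -0.03 under upper quartile scaling (median of all genes -0.13) and -0.02 under quantile normalization without passing.

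Of 16367 genes, 4109 rose and 3571 fell in polysome association (limma, Benjamini-Hochberg adjusted p below 0.05). Of the 4109 that rose, 3719 also rose between the polysome groups and 645 fell between the input groups, and for 245 only the input difference passed. Upper quartile scaling shifted the median by -0.13 and gave 3364 that rose and 4346 that fell. After correction for GC content and length, on 16052 genes, 3441 rose and 2603 fell. By that fit 4760 of the 7680 genes called in association stayed called, against 7594 on the same genes uncorrected.

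Most tested extracellular matrix and synthetase genes rose in polysome association in the knockout and most respiratory subunits fell. Of 33 extracellular matrix and adhesion genes 21 rose and 1 fell (21 and 1 adjusted over the list alone), with L1CAM 1.86-fold and LAMC1 1.77-fold higher. Part of this rise comes from higher levels in wildtype input. The mean log2 value of this list was 0.90 in association, 0.62 between the polysome groups and -0.28 between the input groups. Of 19 aminoacyl-tRNA synthetases 14 rose and 1 fell (14 and 1 adjusted over the list alone), with AARS 3.18-fold and IARS 2.93-fold higher. Of 22 glycolysis genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with PKM 2.71-fold higher. Of 27 lysosome genes 13 rose and 2 fell (13 and 2 adjusted over the list alone), with the peptidase TPP1 3.33-fold higher. Of 76 respiratory subunits 59 fell and 8 rose (60 and 9 adjusted over the list alone), with NDUFA5 5.32-fold and NDUFA4 3.44-fold lower. Of 78 cytosolic ribosomal protein genes 55 fell and 8 rose (56 and 9 adjusted over the list alone), with RPS29 4.09-fold lower. Of 78 mitochondrial ribosomal protein genes 45 fell and 6 rose (48 and 6 adjusted over the list alone), with MRPL32 4.14-fold lower. Of 21 snoRNA host RNAs 18 fell and 0 rose (20 and 1 adjusted over the list alone), with SNHG3 7.46-fold lower. Of 15 nuclear-retained RNAs 11 fell and 2 rose (11 and 3 adjusted over the list alone), with NEAT1 3.19-fold lower. All 9 lists passed by limma camera at the preset correlation, with Benjamini-Hochberg adjusted p from 1.67e-14 for respiratory subunits to 0.0309 for the lysosome. With an estimated correlation 0 did: adjusted p was 0.056 for both noncoding lists, 0.059 for the synthetases, 0.089 for extracellular matrix, 0.42 for glycolysis, 0.43 for respiratory subunits, 0.58 for mitochondrial ribosomal proteins, 0.6 for the lysosome and 0.68 for cytosolic ribosomal proteins. Correction for GC content and length ended the calls of cytosolic ribosomal proteins (median -0.49 before and -0.08 after, adjusted p = 0.485), glycolysis (0.47 and 0.15, adjusted p = 0.0616) and the lysosome (0.33 and 0.26, adjusted p = 0.0732), all by limma camera, and that of L1CAM (adjusted p = 0.0811, limma). The call of the lysosome also ended under upper quartile scaling, quantile normalization, a mean count of at least 100 and without each of 2 single libraries (limma camera adjusted p from 0.0609 to 0.453). Among 10000 lists matched on coding length and GC content, the association medians stood at percentile 60.96 for glycolysis, 47.3 for the lysosome, 94.44 for extracellular matrix (23 of 33 members) and 11.77 for cytosolic ribosomal proteins, inside the central 95% of the matched lists. Respiratory subunits stood at percentile 0 and mitochondrial ribosomal proteins at 0.01, below it. Matched genes need not vary together as the members of these lists do (estimated correlation 0.381 and 0.267), so these percentiles may overstate the departure.

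Within the wildtype, few genes separated the libraries labelled polysome from input. NPY rose 6.26-fold, RNF152 7.16-fold, GRIN3A, a glutamate receptor subunit, 6.17-fold, CA12 5.89-fold and ARHGAP36 5.04-fold. KIRREL1 fell 33.1-fold, COL4A1 16.1-fold, LCP1 14.02-fold, COL4A2 12.2-fold and CRB2 8.94-fold. Adjusted p was at most 5.44e-05 for these 10 genes (limma, Benjamini-Hochberg adjustment), and 8 of the 10 are also among the genes named for input, where they moved the same way, though both comparisons share the wildtype input libraries. LIN28B fell 1.41-fold (adjusted p = 0.0104, limma with Benjamini-Hochberg adjustment), a call lost without wildtype polysome library 2 or 3, and MYCN did not pass (adjusted p = 0.112, same test). In total 453 genes rose and 569 fell (limma, Benjamini-Hochberg adjusted p below 0.05). Leaving out single wildtype libraries lowered the total to as few as 546, without input library 2.

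A minority of the tested snoRNA host and nuclear-retained RNAs, which are noncoding, rose in the libraries labelled wildtype polysome relative to wildtype input. Of 21 snoRNA host RNAs 5 rose and 0 fell (8 and 0 adjusted over the list alone), with SNHG4 1.82-fold and SNHG3 1.49-fold higher. Of 15 nuclear-retained RNAs 5 rose and 0 fell (6 and 0 adjusted over the list alone), with MEG3 1.29-fold and NEAT1 1.30-fold higher. Of 33 extracellular matrix genes 6 fell and 0 rose (6 and 0 adjusted over the list alone). Of 35 genes of the LIN28 and let-7 axis 7 fell and 0 rose (10 and 2 adjusted over the list alone), with IGF2BP1 1.40-fold and IGDCC3 2.19-fold lower. Of 32 genes of ATF4 and the unfolded protein response 6 rose and 0 fell (11 and 2 adjusted over the list alone), with CALR 1.27-fold higher. By limma camera the Benjamini-Hochberg adjusted p at the preset correlation was 6.81e-04 for snoRNA hosts and for extracellular matrix, 0.0172 for nuclear-retained RNAs, 0.0338 for the LIN28 list and 0.0207 for the ATF4 list. These became adjusted p = 0.32, 0.23, 0.23, 0.8 and 0.64 in that order with an estimated correlation. The call of the LIN28 list ended with a mean count of at least 100, with fry and without each of 4 single libraries (limma adjusted p from 0.0576 to 0.155). That of the ATF4 list ended with fry (adjusted p = 0.0537) and without wildtype polysome library 3 (adjusted p = 0.11), that of nuclear-retained RNAs without wildtype input library 2 (adjusted p = 0.0506), and that of SNHG3 without each of 5 single libraries (adjusted p from 0.0529 to 0.0751), all by limma. Cytosolic ribosomal protein genes did not pass (median log2 0.02, adjusted p = 0.832 by limma camera).

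Within the knockout, 4746 genes rose and 4217 fell in the libraries labelled polysome relative to input (limma, Benjamini-Hochberg adjusted p below 0.05). Of 76 respiratory subunits 62 fell and 9 rose (63 and 9 adjusted over the list alone), and of 78 cytosolic ribosomal protein genes 60 fell and 8 rose (60 and 9 adjusted over the list alone), with RPS29 3.92-fold and RPLP1 2.44-fold lower. Of 78 mitochondrial ribosomal protein genes 52 fell and 8 rose (52 and 8 adjusted over the list alone). Of 21 snoRNA hosts 18 fell and 0 rose (19 and 0 adjusted over the list alone), with SNHG3 4.99-fold lower. Of 15 nuclear-retained RNAs 10 fell and 3 rose (10 and 3 adjusted over the list alone), with NEAT1 2.46-fold lower. Of 19 synthetases 14 rose and 2 fell (14 and 2 adjusted over the list alone), with IARS 2.77-fold higher, and of 22 glycolysis genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), with PKM 2.67-fold higher. Of 27 lysosome genes 17 rose and 2 fell (17 and 2 adjusted over the list alone), with TPP1 2.45-fold higher. Of 33 extracellular matrix genes 16 rose and 1 fell (16 and 1 adjusted over the list alone), of 17 immediate early genes 10 and 0 (10 and 0 adjusted over the list alone), with EGR1 3.49-fold higher. Of 29 other mRNAs with a 5 prime TOP motif, a start sequence through which mTOR controls translation, 18 fell and 7 rose (18 and 7 adjusted over the list alone), with NACA 2.05-fold lower and EIF4B 1.82-fold higher. All 11 lists passed by limma camera at the preset correlation, with Benjamini-Hochberg adjusted p from 6.09e-15 for respiratory subunits to 0.0381 for the other TOP mRNAs. With an estimated correlation 0 did: adjusted p was 0.069 for the synthetases and both noncoding lists, 0.22 for glycolysis and extracellular matrix, 0.35 for respiratory subunits, 0.42 for the lysosome, 0.45 for mitochondrial ribosomal proteins, 0.6 for cytosolic ribosomal proteins and immediate early genes and 0.81 for the other TOP mRNAs. LIN28B rose 1.40-fold (adjusted p = 0.00107) and MYCN 1.17-fold (adjusted p = 3.97e-04), both by limma with Benjamini-Hochberg adjustment. Quantile normalization lowered LIN28B to a log2 of 0.21 and ended its call (adjusted p = 0.1), and it turned MYCN to -0.03, whose call also ended under upper quartile scaling (adjusted p = 0.0515, limma). Upper quartile scaling shifted the median by -0.12 and gave 3772 that rose and 5200 that fell. After correction for GC content and length, on 16052 genes, 4094 rose and 3174 fell. By that fit 5848 of the 8963 genes called within the knockout stayed called, against 8855 on the same genes uncorrected. Correction for GC content and length turned MYCN to -0.07 and ended the calls of cytosolic ribosomal proteins (median -0.48 before and -0.10 after, adjusted p = 0.115), extracellular matrix (0.53 and 0.23, adjusted p = 0.118) and immediate early genes (0.41 and 0.31, adjusted p = 0.132), by limma camera for the lists. The call of the other TOP mRNAs ended already on the genes with a GC value, uncorrected (median -0.24, adjusted p = 0.0661), and with the correction their median was -0.02 (adjusted p = 0.775, limma camera). Quantile normalization ended those of the lysosome (adjusted p = 0.2) and of immediate early genes (adjusted p = 0.104), a mean count of at least 100 that of immediate early genes (adjusted p = 0.0965) and leaving out knockout polysome library 1 that of the other TOP mRNAs (adjusted p = 0.0569), all by limma camera.

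**Figure D2:**
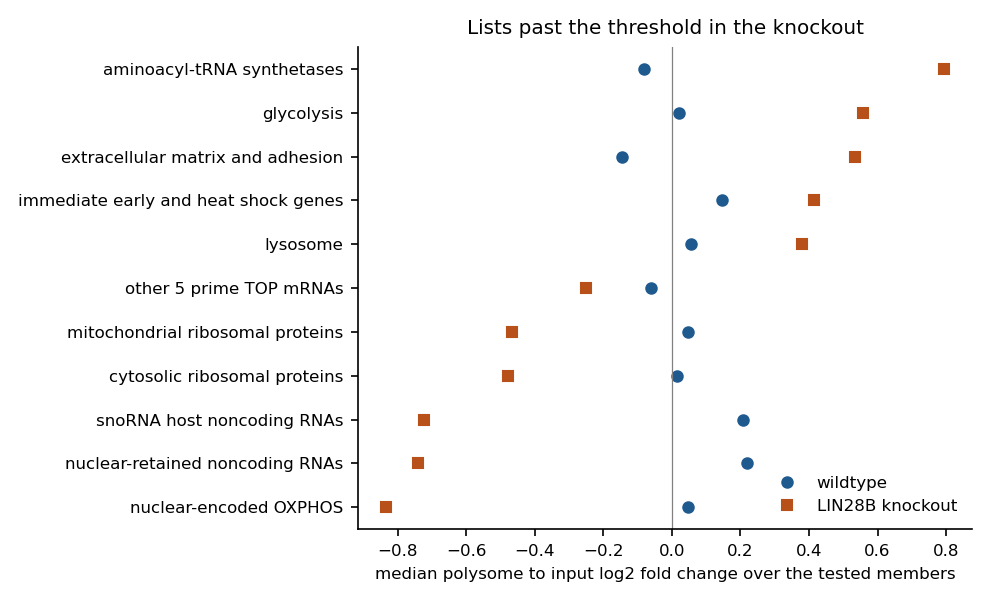
Median polysome to input log2 fold change over the tested members of the 11 lists that passed in the knockout at the preset correlation (0 with an estimated one), for the libraries labelled wildtype (circles) and knockout (squares). Respiratory subunits had a median of -0.83 in the knockout and 0.05 in the wildtype, and aminoacyl-tRNA synthetases 0.79 and -0.08.

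The polysome to input changes of the genotypes ran weakly opposite across genes. Over 10349 genes of mean count of at least 100, the slope of the wildtype change on the knockout change was -0.069 (Pearson r -0.184, Spearman rho -0.206, across genes, which are not independent replicates). Of the 569 genes that fell in wildtype, 332 rose and 62 fell in the knockout, where independent calls would give 165 and 147. Of the 453 that rose in wildtype 162 rose and 127 fell in the knockout, where independent calls would give 131 and 117. Those values take 1 rate over all 16367 tested genes. In a fit to the 10349 genes, 4405 rose and 2922 fell in the knockout, and 447 rose and 560 fell in the wildtype. Independent calls among such genes would give more, so 162 against 131 is not read as an excess. The slope was negative for each library labelled wildtype polysome (-0.095, -0.059 and -0.055). The spread of the change over genes (SD of log2) was 0.26 in the wildtype and 0.68 in the knockout.

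**Figure D3:**
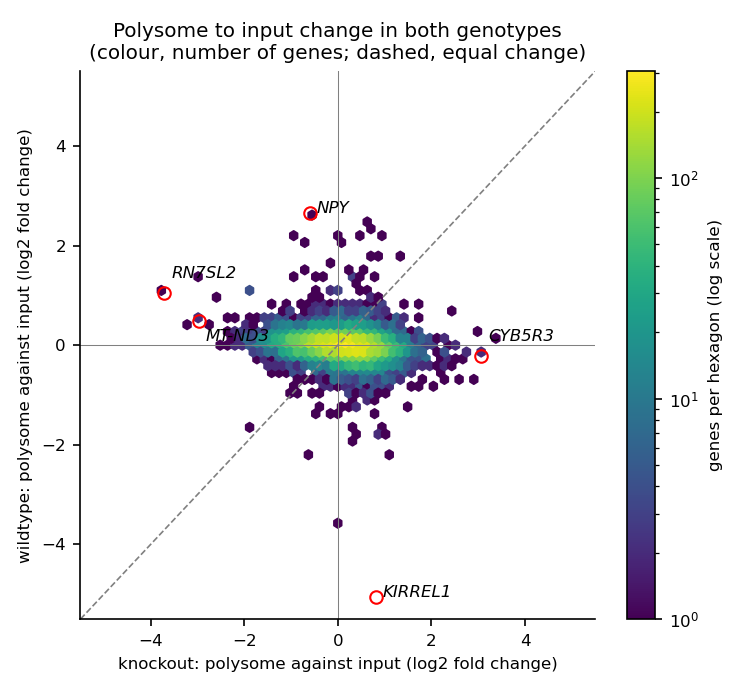
Polysome to input log2 fold change of 10349 genes in the knockout (horizontal) and in the wildtype (vertical), as labelled, with hexagons coloured by the number of genes and 5 genes circled (KIRREL1, of lower mean count, stands outside the hexagons). The cloud is wide along the knockout axis and narrow along the wildtype axis, with a slope of -0.069 against the dashed line of equal change.

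Between libraries, those labelled wildtype polysome stood close to the input libraries. They correlated with wildtype input at 0.972 to 0.975 and with knockout input at 0.971 to 0.977 (Pearson r across genes), while those labelled knockout polysome correlated with all other groups at 0.933 to 0.955. The first principal component held 71.9% of the variance and ran from 50.4 to 55.3 in the libraries labelled knockout polysome and from -22.3 to -12.3 in the other 9.

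**Figure D4:**
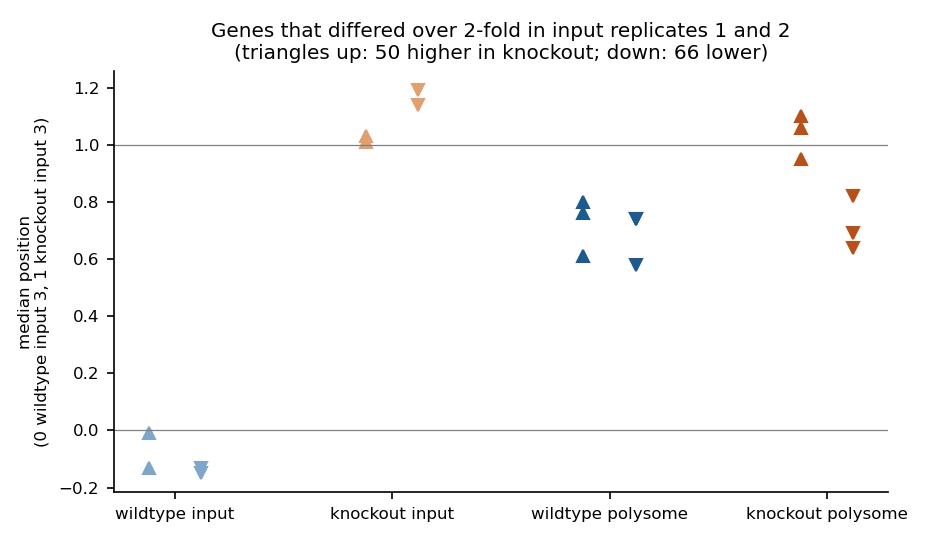
Median position of each library between wildtype input (0) and knockout input (1) for 50 genes that rise (triangles up) and 66 that fall (triangles down) from wildtype to knockout input, with input library 3 of each genotype as the reference. The libraries labelled wildtype polysome lie at 0.66 to 0.74 over both sets, nearer to knockout input.

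In the authors' deposited table, the fold changes of the genotype and fraction comparison ran opposite to the association change given here, with a Pearson r of -0.982 and a Spearman rho of -0.995 over 12952 genes (across genes, not independent replicates). The authors' deposited table holds 6368 genes at an adjusted p below 0.05, of which 6341 were tested here and 6299 also passed here, all 6299 with the opposite sign. In the authors' deposited table NPY stood at 3.25 (SE 0.11) and LIN28B at -0.96 (SE 0.16) on the log2 scale, so that a positive value there means a higher ratio in the wildtype.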

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

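The tests of noncoding RNAs, of an effect of the knockout and of culture states were written after the result was seen. So were those of knockout cells in libraries labelled wildtype and of the TOP motif. The correction for GC content and length was also added then. The results of this part stand here because the polysome to input change differed between the genotypes by a test of the difference itself (the interaction, limma with Benjamini-Hochberg adjustment). This held for 7680 genes and, by limma camera at the preset correlation, 9 lists, of which 0 passed with an estimated correlation (lowest adjusted p = 0.056). In all, 459 genes passed in both genotypes with opposite directions. The differences in log2 change, knockout minus wildtype, were 5.86 for KIRREL1, 4.96 for LCP1, 3.80 for CRB2, 3.62 for COL4A2, 3.51 for TMEM8B and 3.42 for COL4A1. They were -4.77 for RN7SL2, -4.57 for RNF152, -4.26 for RN7SL1, -3.46 for MT-ND3, -3.24 for NPY and -3.17 for ANKRD10-IT1.

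Far fewer genes differed between polysome and input in the wildtype (1022) than in the knockout (8963), each as labelled. Libraries labelled wildtype polysome that hold mostly unfractionated RNA are a candidate explanation. The slope across genes of the wildtype change on the knockout change was -0.069, where a slope under 0.1 had been set for it beforehand. The 36 RNAs of both noncoding lists had a median log2 change of 0.21 in the wildtype, with 9 of them below 0, and -0.73 in the knockout. Whether these RNAs bind ribosomes was not measured, so their level does not by itself mark unfractionated RNA. That explanation leaves open why the slope was negative and why 332 genes fell in the wildtype and rose in the knockout. Bias by GC content and transcript length did not account for the difference in counts (the knockout count stayed 6.4 times the wildtype count after correction). Nor did scaling (at least 6.8 times under 3 other scalings). Coding length was not corrected for. The knockout change followed it more closely (Spearman rho 0.486) than transcript length (0.257, both across genes, which are not independent replicates). Bias by coding length was therefore not tested. An effect of LIN28B loss itself could not be told apart, since the 7680 genes of the interaction rest on polysome preparations that each hold only 1 genotype.

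For genes that changed in input, the libraries labelled wildtype polysome lay toward the knockout, so that KIRREL1, LCP1, COL4A1 and COL4A2 were high in wildtype input only. Noise of the shared wildtype input libraries did not account for this, since the median position, from 0 in wildtype input to 1 in knockout input, stayed at 0.68 with the 116 genes and the reference taken from different input libraries. Input and polysome cultures of the wildtype in different states stay open, with no test that could have supported them: these libraries stood at 0.61 to 0.80 for rising and 0.58 to 0.74 for falling genes (medians over the 3 libraries 0.76 and 0.74), which only restates the pattern. Knockout cells in them stay open as well, with the highest median position at 0.74 against 0.81 for the lowest library labelled knockout polysome. That gap did not hold for falling genes, where the libraries labelled knockout polysome stood at 0.64 to 0.82, against 0.95 to 1.1 for rising genes. With 83 genes chosen on all input libraries, the libraries labelled wildtype polysome stood at 0.63 to 0.76 against 0.90 to 1.02 for the 6 knockout libraries. Those genes and that scale come from the knockout input libraries themselves, which narrows the knockout range. LIN28B, at 5232 against 5779, does not settle whether knockout cells were present.

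Ribosomal protein and respiratory subunit mRNAs were low in the libraries labelled knockout polysome relative to knockout input, with median log2 changes of -0.48 and -0.83. Short and AT-rich transcripts may account for part of it: among 10000 lists matched on coding length and GC content the ribosomal protein median stood at percentile 3.61 and the respiratory median at percentile 0, so the prediction was met for 1 list and not for the other. Matched genes need not vary together as list members do (estimated correlation 0.702 and 0.381), so these percentiles may overstate the departure. Of the lists that rose in the same comparison, extracellular matrix stood at percentile 54.4, the lysosome at 67.8 and glycolysis at 95.89, inside the range of their matched lists. Control of ribosomal proteins through the 5 prime TOP motif could not be told: they fell less than respiratory subunits, which lack the motif (difference of medians 0.36), and other TOP mRNAs had a median of -0.25, which went to -0.02 with correction for GC content and length (adjusted p = 0.775, and 0.81 uncorrected with an estimated correlation, limma camera), while respiratory subunits may have a cause of their own.

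Dividing the same libraries in other ways gave at most 1 gene in input (2746 with the real labels), 0 in polysome (9926), 1 in the wildtype (1022) and 1 in the knockout fraction comparison (8963), each with 1 of 10 splits reaching the real count, and 10 splits are too few for a share under 0.05. For polysome association 2 of 100 splits reached 7680, the real one and one with 8559 that keeps the polysome genotypes and mirrors the input labels. The 10 splits that keep the polysome genotypes gave 6354 to 8559 genes and the other 90 gave 0 to 18, so the count rests mainly on the polysome libraries, and other input labels alone moved it within 6354 to 8559.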

How the results depend on the processing

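Leaving out each library in turn gave 1608 to 3068 genes in input (1608 without knockout input library 2, 1609 without wildtype input library 1), 9106 to 9907 in polysome, 7048 to 7601 in polysome association, 546 to 1021 in the wildtype (546, 642, 676 and 639 without wildtype input library 2, input library 1, polysome library 2 and polysome library 3) and 8104 to 9066 in the knockout fraction comparison, each from a fit with fewer libraries. LIN28B then ranged from 0.054 to 0.347 in polysome and from -0.681 to -0.387 in the wildtype fraction comparison, and the lists called there from 3 to 14. Upper quartile scaling turned MYCN to -0.014 in input, -0.047 in polysome and -0.033 in association, and LIN28B in polysome to -0.03, as it shifts all genes (by -0.191 in polysome and -0.134 in association). Quantile normalization turned MYCN to -0.017 in association, -0.017 in the wildtype and -0.034 in the knockout fraction comparison, and LIN28B in polysome to -0.209, and lowered LIN28B to 0.207 in the knockout fraction comparison, where its call ended. It also moved the mitochondrial DNA list and MT-CO3 to 0.0 and MT-CO1 to 0.134 in input, and the ATF4 and mitotic lists to -0.044 and -0.067 in polysome. Correction for GC content and length, added after the results were seen, turned MYCN to -0.142 in polysome and -0.233 in association, both then past the threshold, and to -0.071 in the knockout fraction comparison and mitochondrial ribosomal proteins to 0.087 in polysome, and put LIN28B at 0.43 in polysome, where it then passed. The cause was not tested. The number of lists called was, in the order input, polysome, association, wildtype and knockout fraction, 0, 3, 0, 0 and 0 with an estimated correlation and 23, 28, 18, 3 and 25 with fry. It was 10 in polysome with a mean of at least 100 and 10 with quantile normalization, 14 in association with no filter and 10 in the wildtype with the GC correction.

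With the replicate number as a block 2608, 9845, 7616, 967 and 8951 genes passed in the same order. Whether the numbers pair the libraries is not given by the labels and could not be told from 3 libraries per group. Deviations of same-numbered libraries correlated at -0.08 to 0.045, and those of other libraries from different groups at -0.037 to 0.074. Analysis of whole reads with count models was not run because whole reads were not recovered. Of other values, 116 counts of genes and 117 counts of lists stayed within 1.5 times, and 6919 values of named genes and 1457 of lists kept direction and call, against 67 and 114 that lost the call.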

Other observations

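Mitochondrial DNA genes, which are translated by mitochondrial ribosomes and not by those in the cytosol, split in the libraries labelled knockout polysome relative to knockout input. MT-ND6 rose by a log2 of 2.28, MT-ND5 by 2.10, MT-CYB by 1.49, MT-ND1 by 0.71, MT-ND4L by 0.71 and MT-ND4 by 0.64, while MT-ND3 changed by -2.97, MT-CO2 by -1.99, MT-ATP8 by -1.12, MT-CO3 by -1.09, MT-ATP6 by -0.91, MT-CO1 by -0.52 and MT-ND2 by -0.23 (limma with Benjamini-Hochberg adjustment, adjusted p at most 0.0130). In the wildtype MT-ND6 stood at -0.06 and MT-ND5 at 0.01, and 10 of the 13 genes, these among them, did not pass. The others passed, each opposite to its change in the knockout: MT-CYB at -0.29 (adjusted p = 8.91e-03), MT-ND3 at 0.48 (adjusted p = 0.0240) and MT-ATP8 at 0.35 (adjusted p = 0.0338, all by limma with Benjamini-Hochberg adjustment). MT-ND5 and MT-ND6 lie next to each other on opposite strands and MT-CYB borders MT-ND6, and the strand of the libraries is not given in the sources used here.

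Nuclear-retained RNAs went both ways in the knockout, with 3 that rose and 10 that fell. MALAT1 rose from 1925 ± 179 in knockout input to 5823 ± 753 normalised counts in the libraries labelled knockout polysome (SD, n = 3), a log2 change of 1.59, with KCNQ1OT1 at 0.67 and LINC00511 at 0.61, while NEAT1 changed by -1.30, MEG3 by -1.17 and MIR17HG by -2.20 (limma with Benjamini-Hochberg adjustment, adjusted p at most 0.0438). Within the knockout the change followed coding length, with median log2 values of -0.39, 0.02, 0.21, 0.35 and 0.54 over 5 equal bins of genes from the shortest to the longest, and 0.02 to -0.05 in the wildtype.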
